A study of Mus musculus with 9 samples.

How the data were processed

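RNA from the hypothalamus of male ICR mice was sequenced on postnatal day 21, in 3 groups of 3 libraries. ICR is an outbred stock. LP pups came from dams on a low-fat diet (10% of energy as fat) and were injected with PBS. HP pups came from dams on a high-fat high-sucrose diet (45% of energy as fat) and were injected with PBS. HA pups came from dams on the high-fat high-sucrose diet and were injected with 4-PBA, the usual short name of 4-phenylbutyric acid. Injections were given daily on postnatal days 4 to 16. Dams started their diet at 5 weeks of age, ate it for 5 weeks before mating and stayed on it through pregnancy and lactation, with 10 pups per litter. Libraries were made from 3 µg of RNA with the NEBNext Ultra RNA kit, per the labels' protocols, which do not describe it as stranded.

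The authors deposited a table of read counts per gene and a table of FPKM values for the same 9 libraries. Per the submitters' processing notes, reads were handled with HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.16.1. The deposited counts are whole numbers for 54532 genes and are not normalized. The deposited FPKM values divide each count by gene length and library size, and a check on the table gave a ratio of deposited FPKM to recomputed FPKM of 0.981 to 1.011. The notes name the build mm9. Of 54409 gene identifiers shared with the GENCODE M21 annotation of GRCm38, however, 53499 (98.3%) had the same start and end in the deposited table, so coordinates are given as deposited and read as GRCm38. Dates stood in place of 27 gene names, and 103 gene identifiers repeated a name. Genes were therefore followed by identifier.

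Total counts lay between 18226924 and 21823961 per library. Counts were compared between all pairs of libraries within a group by chi-square, over genes with at least 20 counts. The statistic per degree of freedom lay between 4.73 and 25.83, so no pair differed by as little as sampling noise and all 9 libraries were kept. Nothing in the labels says whether the pups of a group came from separate litters, so p-values measure the spread between these libraries, which may be partly technical or shared within litters. Libraries also carry a code in their titles whose meaning is not stated. It was Lg42 for LP replicate 1 and Lg63 for LP replicates 2 and 3. It was Hg43 for replicates 1 and 2 and Hg13 for replicate 3 in both HP and HA. Because the codes differ between diets, code and diet cannot be told apart in comparisons with LP.

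The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, fitted to the counts of all 9 libraries with the group as the only term. Genes were filtered with filterByExpr, which kept 17546, and libraries were scaled by TMM. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The common dispersion was 0.0199, a biological coefficient of variation of 14.1%. Log2 fold changes are the edgeR estimates, and their standard error (SE) is the size of the estimate divided by the square root of F. CPM values use TMM-scaled library sizes, and log2 CPM values have a prior count of 2. Comparisons were HP against LP, HA against HP and HA against LP. An exact permutation test of 3 libraries against 3 cannot go below a two-sided p of 0.1, so none was used for single genes.

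A total of 45 gene lists were fixed before the data were examined, and 44 of them were tested. The remaining list holds genes of the X and Y chromosomes and served to check the sex of the libraries. Lists were tested with camera from limma 3.58.1 with a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the 44 lists. Each list was also tested with the correlation estimated from its residuals, and with fry. No list passed 0.05 with an estimated correlation or with fry's directional test in any comparison. The mixed test of fry, for change in either direction, passed 3 lists for HP against LP, 0 for HA against HP and 5 for HA against LP. The 3 were cytosolic heat shock proteins, neuroendocrine hormones and the thyroid hormone pathway. The 5 were immediate early genes, energy balance receptors and signalling, the thyroid hormone pathway, neuroendocrine hormones and cytosolic ribosomal proteins. Members of a list were counted after adjustment over all genes and after adjustment over the list alone. Libraries were placed on a list by the mean deviation of its members' log2 CPM from their mean over the 9 libraries.

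Genes named in the text were chosen by a rule set before the data were examined. It takes the 10 largest rises and 10 largest falls among called genes with at least 1 CPM in the higher group and no overlap between libraries, passing over gene models without a name and pseudogenes. It takes up to 4 members of smallest p from each called list. It always takes Agrp, Npy, Pomc, Cartpt, Lepr, Mc4r, Hspa5, Ddit3, Atf4 and Xbp1. If fewer than 10 genes pass in a direction, it takes the named genes of smallest p up to 10, which are given as values and not as changes. The text gives a selection of these genes, and some that the rule takes are not reported here. The pseudogene Gm6472 and library markers fall outside the rule, and Gm6472 was named after its values had been seen.

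Correlations of log2 fold changes between comparisons that share libraries were set against 100 simulated data sets in which no group differed. Whether replicate numbers pair libraries across groups was checked from deviations from the group means. For HA and LP, libraries of the same number correlated at 0.256, 0.144 and 0.486, all above 0.1, so these groups were treated as possibly paired although no label states a pairing. HA replicate 2 correlated best with LP replicate 1. LP replicate 3 and HA replicate 3 were also the libraries highest on the meningeal fibroblast markers, with mean deviations of 2.118 and 2.727. A tissue signal shared by these libraries could give such correlations without any pairing, so the check cannot show that the groups are paired. The other comparisons did not meet that bound.

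Alternatives fixed before the data were examined were other filters for low counts, RLE scaling, scaling by library totals, DESeq2 1.42.0, limma-voom, robust and legacy edgeR fits, a fit to the 6 libraries compared, the replicate number as a block, a gene length offset, other thresholds, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the title code as a term in the 6 HP and HA libraries, and leaving out each library in turn. Fits without LP replicate 3 and HA replicate 3 and without LP replicates 1 and 2 were added after seeing the data. On simulated counts for 17546 genes, with 50 genes changed at each fold size, edgeR recovered 54% of changes of 1.5-fold, 54% of 2-fold, 82% of 3-fold and 92% of 4-fold for HP against LP, with 6 false calls. For HA against HP it recovered 52%, 54%, 80% and 90%, with 10 false calls. For HA against LP, simulated with 0 changed genes, it made 0 calls. On the same counts DESeq2 made 25, 26 and 7 false calls for HP against LP, HA against HP and HA against LP, and limma-voom 4, 6 and 0. DESeq2 recovered 58% to 92% of the changes for HP against LP and 60% to 90% for HA against HP, by fold size. False calls in these comparisons therefore stood beside many true ones. On the real counts DESeq2 was run without filterByExpr and gave p-values for 32580 genes. Its simulated and real calls therefore rest on different gene sets. The members of the glycolysis list were also shifted in the simulated HP libraries. Transcript sequences were matched with blastn 2.17.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.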

Results

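Gene expression was measured in the hypothalamus, the brain region that controls feeding, energy use and pituitary hormones, in 9 libraries from male ICR pups on postnatal day 21. LP, HP and HA had 3 libraries each. LP and HP differed in the diet of the dam, and HP and HA differed in the injections the pups received on postnatal days 4 to 16. The compound given to HA, 4-PBA, is known as a chemical chaperone that eases protein folding stress in the endoplasmic reticulum and as an inhibitor of histone deacetylases. Total counts per library lay between 18226924 and 21823961. Xist, which is expressed from the inactive X chromosome of females, lay between 0 and 0.19 CPM, and the Y-linked gene Ddx3y between 104 and 118 CPM.

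Libraries of a group differed in genes of neighbouring tissue. Adora2a, an adenosine receptor gene of striatal neurons, stood at 15.7 CPM in LP replicate 1, 23.6 CPM in LP replicate 2 and 3.76 CPM in LP replicate 3, against 2.39 to 4.21 CPM in the 6 libraries of HP and HA. Dcn, a matrix gene of meningeal fibroblasts, stood at 45.4 CPM in LP replicate 3 and 124 CPM in HA replicate 3, against 12.8 to 20.4 CPM in the other libraries. The pituitary hormone gene Gh reached 16.2 CPM in HA replicate 3 and at most 2.53 CPM elsewhere. The principal component of largest variance held 34% of it, with scores of 51.5 for HA replicate 3 and 31.6 for LP replicate 3 and between -21.4 and -1.9 for the other libraries.

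The comparison of HP with LP asked which hypothalamic genes differed between pups of dams on the high-fat high-sucrose diet and pups of dams on the low-fat diet. Nub1, whose product lowers the levels of NEDD8 and its conjugates, fell from 71.6 ± 0.368 CPM in LP to 40.8 ± 1.54 CPM in HP (SD, n = 3 each). Genes of cytosolic heat shock proteins and of the interferon response lay higher in HP, and markers of the striatum lay lower. With an estimated correlation these 3 list calls were lost (adjusted p = 0.12, 0.791 and 0.18), and LP replicate 3 stood at -0.111 on the striatal markers against 0.522 and 0.728 in LP replicates 1 and 2. The appetite neuropeptides and the receptors of energy balance were not called as lists.

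Nub1 (ENSMUSG00000028954, chromosome 5, 24685532 to 24710378, GRCm38, protein-coding) had a log2 fold change of -0.81 (SE 0.045) in HP against LP, with an adjusted p of 9.61e-05 (edgeR, Benjamini-Hochberg). It overlaps an antisense gene, Gm26648, which had a mean of 20.9 counts against 1197.9 for Nub1, and without strand reads of the pair cannot be told apart. The only other gene called was Gm6472 (ENSMUSG00000095597, chromosome X, 152909505 to 152910155), a transcribed processed pseudogene chosen for naming after its values were seen. It rose from 47.7 ± 2.44 CPM to 71.3 ± 4.74 CPM (SD, n = 3 each), a log2 fold change of 0.58 (SE 0.064) with an adjusted p of 0.0313 (edgeR, Benjamini-Hochberg). The best match of its sequence among transcripts of other genes was Rps7, a ribosomal protein gene (ENSMUSG00000061477, chromosome 12, 28630854 to 28635953), with 99.4% identity over all 651 bases. Other transcripts matched closely as well, such as Gm9493 with 98.9% identity over 87.6% of the sequence. Counts of Rps7 and Gm6472 are therefore uncertain, and their sum leaves out the other matches. Rps7 stood at 173.5 ± 6.26 CPM in LP and 142.3 ± 4.09 CPM in HP, with an adjusted p of 0.168, and the summed count of both had a log2 fold change of -0.053 (SE 0.041, adjusted p = 0.892).

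**Figure D1:**
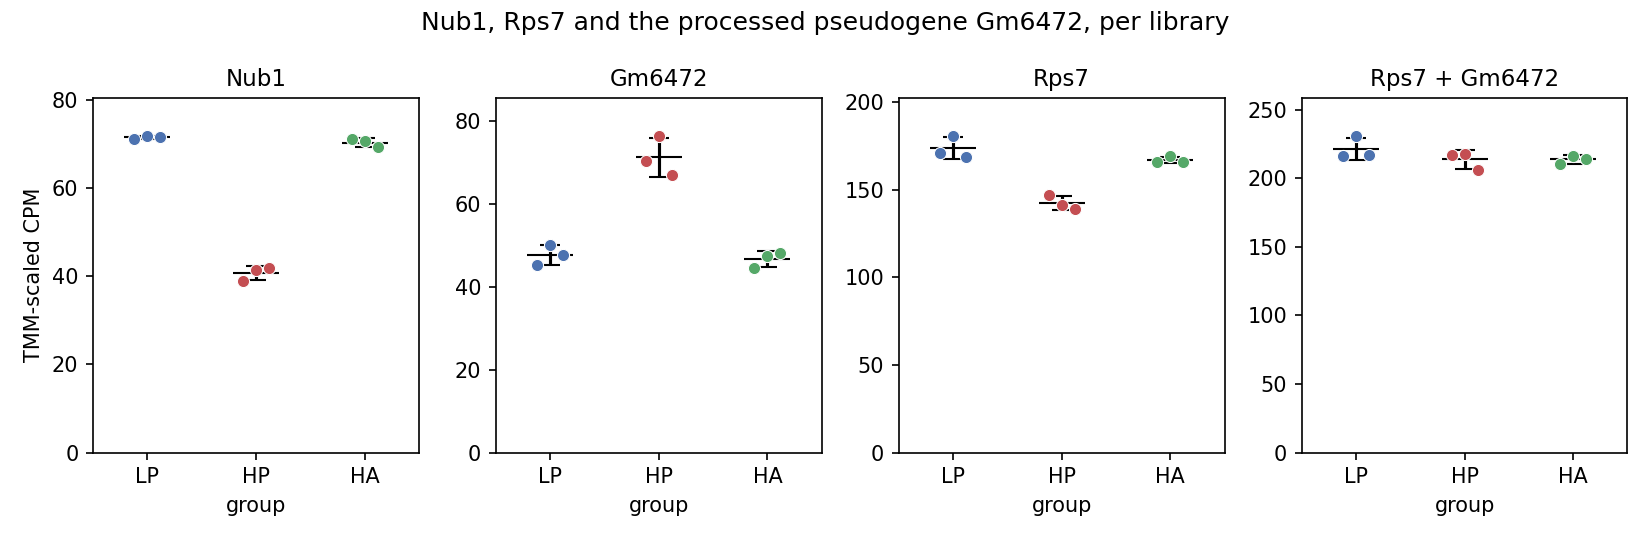
TMM-scaled CPM of Nub1, Gm6472, Rps7 and the sum of Rps7 and Gm6472 by group (LP, HP, HA); each point is a library, the horizontal line the mean and the bars the SD of 3 libraries. The HP libraries of Nub1 lie between 39.0 and 41.8 CPM, below the other 6 libraries at 69.3 to 71.9 CPM, and the summed count of Rps7 and Gm6472 overlaps between the groups.

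Other named genes of small p did not pass the adjustment over all genes. Chga, which encodes the secretory granule protein chromogranin A (chromosome 12, 102554969 to 102565028), stood at 314.1 ± 10.3 CPM in LP and 250.2 ± 2.91 CPM in HP (adjusted p = 0.168, edgeR). Gstp1, a glutathione transferase gene (chromosome 19, 4035407 to 4037921), stood at 96.1 ± 19.2 and 158.1 ± 13.1 CPM (adjusted p = 0.244). Kcnj4, a potassium channel gene (chromosome 15, 79483714 to 79505241), stood at 14.8 ± 4.0 and 5.97 ± 1.13 CPM (adjusted p = 0.244). Fras1, Gpcpd1, Zfp92 and Casc4 had adjusted p between 0.221 and 0.339 and log2 fold changes between -0.46 and 0.30. DESeq2 called all 7 of these genes, with adjusted p up to 0.049, and Rps7 at 3.74e-05. On simulated counts for this comparison, in which 50 genes changed at each fold size, DESeq2 made 25 false calls and edgeR 6. Without LP replicate 3 edgeR called Gstp1 and Kcnj4 (adjusted p = 0.00715 and 0.0171), and without HA replicate 3 it called Chga (adjusted p = 0.0245). Gstp-ps, a name outside the rule, was also called by DESeq2 and without LP replicate 3. Whether Gstp-ps shares reads with Gstp1 was not tested.

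All 15 members of the list of cytosolic heat shock proteins, which are chaperones, had a higher estimate in HP, with a median log2 fold change of 0.21 (camera, adjusted p = 2.99e-17). That adjusted p was 0.12 with an estimated correlation and 0.0379 with the mixed test of fry. Over all genes 0 members changed, and 5 were higher when adjusted over the list alone. Dnajb1 stood at 95.8 ± 5.71 CPM in LP and 125.2 ± 10.1 CPM in HP, Hsph1 at 369.5 ± 22.4 and 445.9 ± 26.2 CPM, and Hspa1b at 16.6 ± 3.46 and 27.0 ± 2.26 CPM. DESeq2 called Dnajb1 and Hsph1 higher (adjusted p = 0.00189 and 0.00442).

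Of the interferon response list, 24 of 28 members had a higher estimate in HP (median 0.30, camera adjusted p = 1.8e-10). With an estimated correlation the adjusted p was 0.791. No member changed over all genes, and 4 were higher when adjusted over the list alone. Irf7, a transcription factor of the interferon response, stood at 1.93 ± 0.444 CPM in LP and 6.38 ± 1.32 CPM in HP, a log2 fold change of 1.73 (SE 0.307) with an adjusted p of 0.339 (edgeR). Irf7 overlaps Phrf1 on the other strand, which had a mean of 1102.9 counts against 69.7 for Irf7. Mx2 stood at 1.93 ± 0.231 and 3.45 ± 0.433 CPM. DESeq2 called Irf7 (adjusted p = 0.000564). Without LP replicate 3 the median of the list was 0.73, with an adjusted p of 1.39e-16, and without LP replicates 1 and 2 it was 0.15, with an adjusted p of 0.489.

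All 17 striatal markers had a lower estimate in HP (median -0.34, camera adjusted p = 2.99e-17; 0.18 as adjusted p with an estimated correlation). Over all genes 0 changed, and 8 were lower when adjusted over the list alone. Adora2a stood at 15.7, 23.6 and 3.76 CPM in the LP libraries and at 2.71 ± 0.286 CPM in HP. Ppp1r1b, which encodes DARPP-32, stood at 49.2 ± 34.4 and 10.2 ± 1.66 CPM. Without LP replicates 1 and 2, which leaves LP with 1 library assumed to vary like the others, the adjusted p was 0.289 and the median -0.109. Without LP replicate 2 alone the median was -0.225, and without LP replicate 3 edgeR called Adora2a and Ppp1r1b lower (adjusted p = 0.00153 and 0.00256). Genes of monoaminergic signalling, a list that includes dopamine receptors, were lower for 20 of 22 members (camera adjusted p = 0.000455; 0.12 as adjusted p with an estimated correlation). Drd2 stood at 21.7 ± 2.81 CPM in LP and 15.5 ± 2.65 CPM in HP.

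All 23 myelin genes of oligodendrocytes had a higher estimate in HP (median 0.20, camera adjusted p = 1.99e-09; 0.791 as adjusted p with an estimated correlation), and 0 changed over all genes or when adjusted over the list alone. The median was 0.106 without LP replicate 1 and 0.41 without LP replicate 2. The unfolded protein response, the set of genes that answers misfolded protein in the endoplasmic reticulum, had 27 of 35 members higher (median 0.09, adjusted p = 6.01e-06; 0.791 as adjusted p with an estimated correlation), also with 0 changed either way. Its member Hspa5, the chaperone BiP, stood at 628.7 ± 28.5 CPM in LP and 736.2 ± 24.2 CPM in HP, and Hsp90b1 at 368.2 ± 28.8 and 426.5 ± 15.3 CPM. Ddit3 stood at 26.9 ± 1.7 and 26.7 ± 1.17 CPM, Atf4 at 107.2 ± 6.65 and 105.7 ± 3.78 CPM, and Xbp1 at 118.1 ± 6.96 and 136.5 ± 2.78 CPM. Ddit3 overlaps Mars on the other strand.

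Among feeding genes, Agrp, the peptide gene of hunger-promoting arcuate neurons, stood at 11.2 ± 1.72 CPM in LP and 12.4 ± 3.53 CPM in HP. The gene model of Agrp overlaps Ctcf and Ripor1 on the other strand, with 1245.9 and 1234.8 counts on average against 244.6, which makes its value uncertain. Npy stood at 30.8 ± 2.41 and 27.8 ± 4.59 CPM, Pomc, the precursor of satiety-promoting melanocortins, at 50.04 ± 1.77 and 63.5 ± 14.1 CPM, and Cartpt at 85.2 ± 3.42 and 89.1 ± 15.7 CPM. The leptin receptor gene Lepr stood at 10.4 ± 5.86 and 7.11 ± 0.434 CPM and the melanocortin receptor gene Mc4r at 5.73 ± 1.85 and 5.31 ± 0.891 CPM. Lepr was higher in LP replicate 3 and HA replicate 3, the libraries highest in meningeal markers, than in all others. None of these 6 genes passed (edgeR, adjusted p between 0.81 and 0.963). The list of appetite neuropeptides had a camera adjusted p of 0.317 and that of energy balance receptors and signalling 0.601, the latter with a median of -0.006 and a mean of 0.01.

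The other 9 lists called in HP against LP were lost without at least 1 library, and their adjusted p with an estimated correlation lay between 0.791 and 0.841. Respiratory chain genes of the mitochondrial genome were lower (adjusted p = 0.000108; 0.173 without LP replicate 2). Meningeal fibroblast markers were lower (adjusted p = 0.017) and matrix and collagen genes were lower (adjusted p = 0.0481; 0.0622 when scaled by library totals), and both turned without LP replicate 3, the LP library highest in Dcn. Without it meningeal markers were called higher (adjusted p = 0.0378, median 0.561), and matrix genes had a median of 0.134 (adjusted p = 0.188). Their calls were also lost without HP replicate 1 or HP replicate 2, with adjusted p up to 0.136 and 0.252. Glutamatergic synapse genes (adjusted p = 0.0162) and markers of cortex and hippocampus (0.0237) were lower, and both were lost without LP replicate 1, LP replicate 2 or HP replicate 2, with adjusted p up to 0.582 and 0.178. Sterol synthesis genes were higher (0.017; up to 0.684 without LP replicate 1 or LP replicate 3). Proteasome subunits were higher (0.0414; 0.0512 when scaled by library totals and up to 0.37 without LP replicate 3, HP replicate 1, HP replicate 3 or HA replicate 3). Oligodendrocyte precursor markers were higher (0.0468; up to 0.302 without LP replicate 1, LP replicate 3, HP replicate 1 or HP replicate 2). Blood cell markers were lower (0.0468; 0.0591 when scaled by library totals and 0.107 without HP replicate 3). Without LP replicate 3 camera gave them the opposite direction, with an adjusted p of 0.88 and a median of -0.167.

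**Figure D2:**
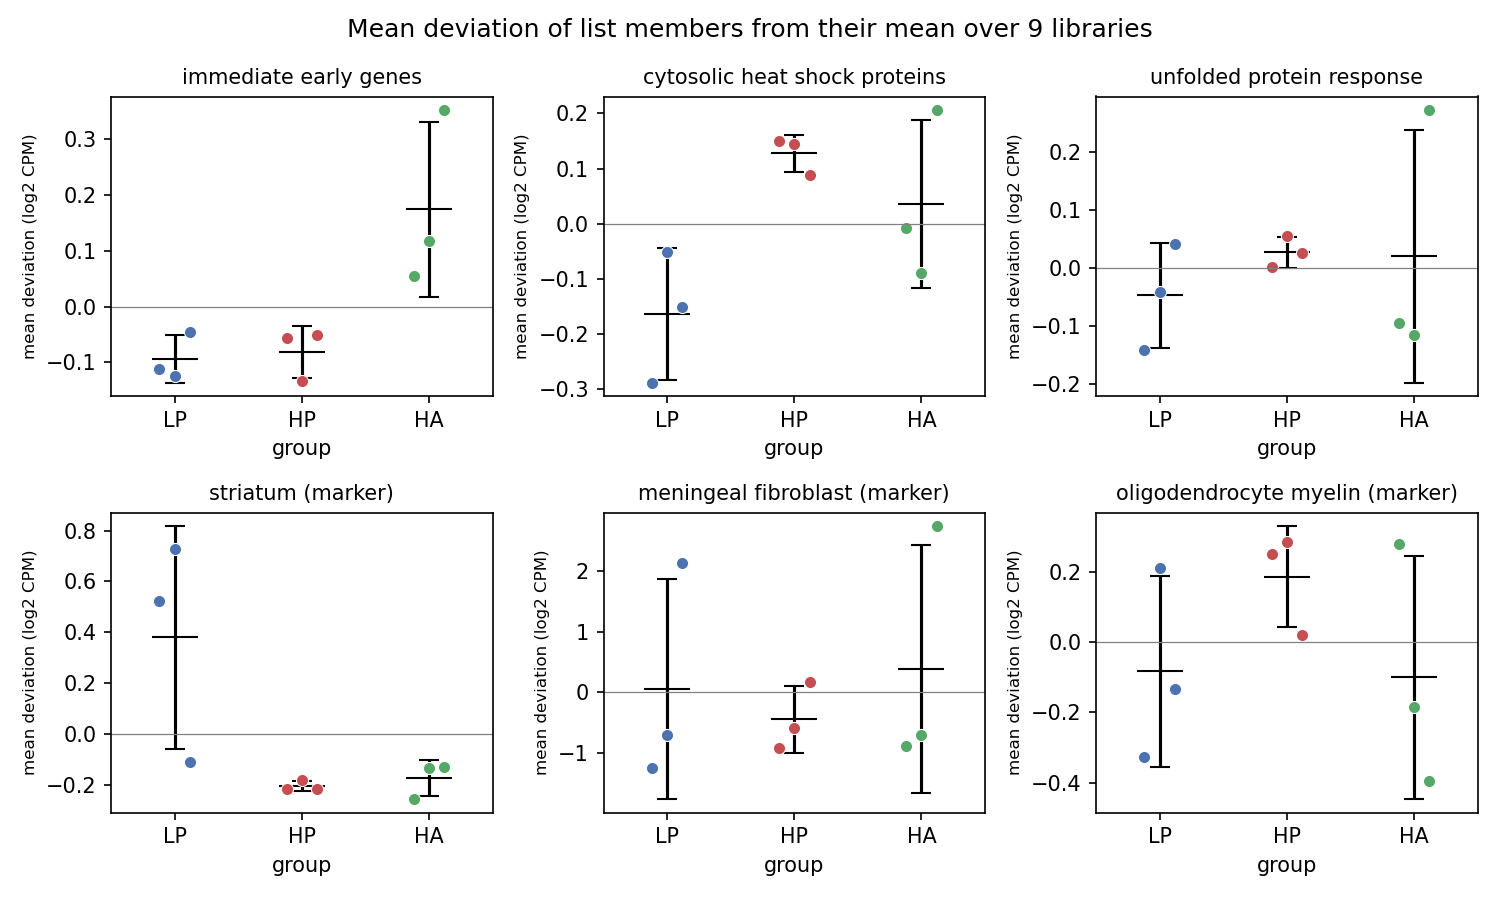
Mean deviation of the members of 6 gene lists from their mean over the 9 libraries, in log2 CPM, by group (LP, HP, HA); each point is a library, the horizontal line the group mean and the bars the SD. LP replicates 1 and 2 stand at 0.522 and 0.728 on the striatal markers, and LP replicate 3 and HA replicate 3 at 2.118 and 2.727 on the meningeal markers.

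In this comparison edgeR called 2 of 17546 genes, 1 higher and 1 lower, and 1081 had an unadjusted p under 0.05 where chance would give 877. DESeq2 called 32 genes, and limma-voom called 2. In simulation DESeq2 made 25 false calls while it recovered 58% to 92% of 50 changed genes per fold size. EdgeR made 6 false calls and limma-voom 4. With so many simulated changes, and with the real DESeq2 run made on unfiltered genes, these numbers do not give the share of false calls among the 32. The number called was 22 without LP replicate 3, 7 without HP replicate 3 or HA replicate 3, and 1 without LP replicate 2, HP replicate 1, HP replicate 2, HA replicate 1 or HA replicate 2, and 48 without LP replicate 3 and HA replicate 3. Nub1 remained called whichever single library was left out, while Gm6472 had an adjusted p of 0.108 without LP replicate 1, 0.109 without LP replicate 2, 0.231 without HP replicate 1, 0.174 without HP replicate 2, 0.0563 without HA replicate 1 and 0.109 without HA replicate 2.

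The comparison of HA with HP asked which genes differed with 4-PBA among pups of dams on the high-fat high-sucrose diet. Nub1 rose from 40.8 ± 1.54 CPM in HP to 70.4 ± 0.97 CPM in HA (SD, n = 3 each), next to the 71.6 ± 0.368 CPM of LP. Immediate early genes, which neurons switch on within minutes of stimulation, lay higher in HA, and myelin genes lay lower, with HA replicate 1 within the range of HP. Both list calls were lost with an estimated correlation (adjusted p = 0.317 and 0.702). Genes of the matrix and meninges also lay higher on average in HA, a difference that rested on HA replicate 3 and was likewise lost with an estimated correlation (adjusted p = 0.702 and 0.786). HA replicate 3 stood at 2.727 on the meningeal markers, next to 2.118 in LP replicate 3 and at most 0.171 in the other libraries.

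Nub1 had a log2 fold change of 0.79 (SE 0.045) with an adjusted p of 0.000131 (edgeR, Benjamini-Hochberg), and all HA libraries were above all HP libraries. Gm6472 fell from 71.3 ± 4.74 to 46.8 ± 2.0 CPM (log2 fold change -0.61, SE 0.064, adjusted p = 0.0207). Its near-identical partner Rps7 stood at 142.3 ± 4.09 CPM in HP and 166.8 ± 1.85 CPM in HA (adjusted p = 0.847), and the summed count had a log2 fold change of 0.004 (SE 0.041). HP and HA hold the same title codes. The log2 fold change of Gm6472 was -0.608 in the fit to these 6 libraries, with an adjusted p of 0.0657, and -0.608 with the code as a term as well, with an adjusted p of 0.0747. Casc4 (chromosome 2, 121866970 to 121936220) stood at 164.9 ± 3.68 and 136.8 ± 2.54 CPM (adjusted p = 0.165). Man2b2, a mannosidase gene, stood at 15.7 ± 0.254 and 29.5 ± 2.64 CPM, Akr1c14, a steroid dehydrogenase gene, at 1.58 ± 0.0868 and 3.36 ± 0.0844 CPM, and the integrin gene Itga4 at 4.42 ± 0.285 and 7.33 ± 0.632 CPM, each with an adjusted p of 0.847. Rps6kc1, Itpk1 and Rcn1 had log2 fold changes of -0.30, -0.30 and 0.29 at the same adjusted p. DESeq2 called Casc4, Man2b2, Rps6kc1 and Rps7 (adjusted p between 0.000139 and 0.0439). EdgeR called Man2b2 without LP replicate 1 (adjusted p = 0.0252) and in the fit to 6 libraries (0.0464). Both of these fits leave out LP replicate 1, where Man2b2 stood at 27.5 CPM, against 15.0 and 17.4 CPM in LP replicates 2 and 3. Its high level was thus not confined to HA.

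Of the immediate early genes, 23 of 24 had a higher estimate in HA (median 0.30, camera adjusted p = 3.02e-10). The adjusted p was 0.317 with an estimated correlation. Over all genes 0 changed, and 5 were higher when adjusted over the list alone. Nr4a1, an orphan nuclear receptor gene (chromosome 15, 101254269 to 101274795), stood at 19.1 ± 1.21 CPM in HP and 26.2 ± 1.14 CPM in HA. Nr4a3 stood at 14.7 ± 0.67 and 20.1 ± 2.86 CPM, Sik1 at 28.6 ± 1.07 and 35.3 ± 3.71 CPM, and Junb at 29.5 ± 2.86 and 37.7 ± 3.98 CPM. Junb overlaps Prdx2, which had 4434.7 counts on average against 607.0 for Junb. Without HA replicate 3 the median of the list was 0.192, with an adjusted p of 4.89e-05. Without LP replicate 3 and HA replicate 3 it was 0.191, with an adjusted p of 9.77e-06.

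All 23 myelin genes had a lower estimate in HA than in HP (median -0.27, camera adjusted p = 3.02e-10; 0.702 as adjusted p with an estimated correlation), with 0 changed over all genes or adjusted over the list alone. Mobp stood at 2080 ± 199 CPM in HP and 1558 ± 431 CPM in HA. The HA libraries differed on this list, with mean deviations of 0.279 in HA replicate 1, -0.185 in HA replicate 2 and -0.396 in HA replicate 3, against 0.251, 0.283 and 0.02 in HP replicates 1 to 3. The median was -0.507 without HA replicate 1 and -0.123 without HA replicate 3, both still called (adjusted p = 2.49e-31 and 0.0127). Proteasome subunits, which with immediate early and myelin genes were called whichever single library was left out, were lower for 31 of 37 members (median -0.048, adjusted p = 0.00291; 0.702 as adjusted p with an estimated correlation). Scaled by library totals their median was -0.028.

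All 24 matrix and collagen genes (camera adjusted p = 1.48e-08) and all 20 meningeal fibroblast markers (5.75e-05) had a higher estimate in HA, with adjusted p of 0.702 and 0.786 with an estimated correlation. Without HA replicate 3, which had 124 CPM of Dcn, their adjusted p were 0.966 and 0.205 and their medians -0.093 and -0.401. Without LP replicate 3 and HA replicate 3 the meningeal markers were called lower, with an adjusted p of 0.000939. Endothelial and mural markers and inflammatory genes were also higher (0.000628 and 0.0041), and both were lost without HA replicate 3 (0.937 and 0.733). Their adjusted p with an estimated correlation was 0.702.

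Among stress lists, cytosolic heat shock genes were lower for 13 of 15 members (adjusted p = 0.00291; 0.702 as adjusted p with an estimated correlation), a call lost without HP replicate 1 or HA replicate 2, with an adjusted p up to 0.148. The unfolded protein response was called lower at an adjusted p of 0.0449 (0.859 with an estimated correlation and 0.0733 when scaled by library totals). Its median was -0.024 and its mean 0.045, so they differ in sign, and the call was lost without LP replicate 3, HP replicate 1, HP replicate 2, HA replicate 1 or HA replicate 2, with an adjusted p up to 0.733 and a median of -0.003 without HA replicate 2. Without HA replicate 3 the list was called lower with an adjusted p of 3.41e-11 and a median of -0.086, and without LP replicate 3 and HA replicate 3 with 6.95e-11 and -0.086. HA replicate 3 had a mean deviation of 0.272 on this list and 0.206 on the heat shock list, while the other HA libraries lay between -0.116 and -0.008 on both. Hspa5 stood at 736.2 ± 24.2 CPM in HP and 652.0 ± 78.3 CPM in HA, Xbp1 at 136.5 ± 2.78 and 116.7 ± 26.3 CPM, Atf4 at 105.7 ± 3.78 and 108.2 ± 0.437 CPM, and Ddit3 at 26.7 ± 1.17 and 26.8 ± 0.967 CPM. Xbp1 was not called over all 9 libraries (log2 fold change -0.228, adjusted p = 0.847, edgeR), but was called lower without HA replicate 3 (-0.424, adjusted p = 0.0355) and without LP replicate 3 and HA replicate 3 (adjusted p = 0.0226).

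Glucocorticoid-responsive genes were called lower (adjusted p = 0.000628; 0.702 as adjusted p with an estimated correlation), with 4 lower when adjusted over the list alone, and lost without HA replicate 1 (0.227). Their median was -0.137, and it was -0.05 without HP replicate 2, -0.336 without HA replicate 3 (adjusted p = 1.53e-09) and -0.337 without LP replicate 3 and HA replicate 3 (2.89e-11). Zbtb16 stood at 46.0 ± 5.45 CPM in HP and 30.8 ± 6.61 CPM in HA. The interferon response list was called lower (0.00483; 0.859 as adjusted p with an estimated correlation) and lost without HP replicate 1 or HA replicate 1, with adjusted p of 0.0561 and 0.461 and medians of 0.015 and 0.075, against -0.082 with all libraries. The median was -0.023 without HP replicate 2, -0.478 without HA replicate 3 (adjusted p = 5.8e-10) and -0.482 without LP replicate 3 and HA replicate 3 (3.37e-11). Irf7 stood at 6.38 ± 1.32 and 2.67 ± 1.13 CPM.

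Feeding genes did not pass in HA against HP (edgeR, adjusted p between 0.847 and 0.943). Agrp stood at 12.4 ± 3.53 CPM in HP and 14.1 ± 2.93 CPM in HA, Npy at 27.8 ± 4.59 and 35.5 ± 7.13 CPM, Pomc at 63.5 ± 14.1 and 79.0 ± 13.4 CPM, and Cartpt at 89.1 ± 15.7 and 100.1 ± 5.44 CPM. Lepr stood at 7.11 ± 0.434 and 12.3 ± 8.95 CPM, with HA replicate 3 above the other HA libraries, and Mc4r at 5.31 ± 0.891 and 4.82 ± 0.975 CPM. The list of appetite neuropeptides had a camera adjusted p of 0.788 and that of energy balance receptors and signalling 0.884. For the appetite list the median was 0.019 and the mean -0.077, which differ in sign.

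The remaining 7 called lists had adjusted p between 0.702 and 0.859 with an estimated correlation. Cytosolic ribosomal proteins were higher for 56 of 75 members (adjusted p = 0.000315; 0.286 without HP replicate 3). Rps7 is among them, and was the 1 member higher when adjusted over the list alone. The other 6 calls were lost without HP replicate 1 and without HA replicate 3. Cell cycle genes (adjusted p = 0.0204, up to 0.449 without a library) and pituitary markers (0.0453, up to 0.264) were higher. Lower lists were presynaptic vesicle release (0.0121, up to 0.937), oligodendrocyte precursor markers (0.0162, up to 0.934), GABAergic synapse (0.0309, up to 0.792) and mitochondrial-encoded respiratory chain genes (0.0453, up to 0.26). The last had a median of -0.083 and a mean of 0.042. Presynaptic genes and pituitary markers were also lost without HP replicate 3, pituitary markers without LP replicate 3 or HA replicate 2, and the mitochondrial list without LP replicate 3, HP replicate 2, HP replicate 3 or HA replicate 2. Scaled by library totals, cell cycle (0.0531), GABAergic synapse (0.0578) and pituitary (0.0929) lists were not called.

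For HA against HP edgeR called 2 genes, 1 higher and 1 lower, and 915 had an unadjusted p under 0.05 where chance would give 877. DESeq2 called 8, and limma-voom called 2. In simulation DESeq2 made 26 false calls while it recovered 60% to 90% of 50 changed genes per fold size. EdgeR made 10 false calls and limma-voom 6. With so many simulated changes, and with the real DESeq2 run made on unfiltered genes, these numbers do not give the share of false calls among the 8. The number called was 9 without HA replicate 3, 4 without HP replicate 3, and 1 without LP replicate 3, HP replicate 1, HP replicate 2, HA replicate 1 or HA replicate 2, each of which ended the call of Gm6472 (adjusted p between 0.0556 and 0.179), and 11 without LP replicate 3 and HA replicate 3. The number of lists called was 18, against 8 without HA replicate 3, 9 without HP replicate 1 and 10 without LP replicate 3 and HA replicate 3.

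The comparison of HA with LP asked which differences from the low-fat group were present in pups that had both the dam's high-fat high-sucrose diet and 4-PBA. Immediate early genes and heat shock chaperones lay higher in HA than in LP, and striatal markers, monoaminergic genes and respiratory chain genes of the mitochondrial genome lay lower. None of these 5 list calls held with an estimated correlation (adjusted p = 0.0874, 0.309, 0.215, 0.0874 and 0.301), and the libraries of HA and LP overlapped on the heat shock list. On the striatal markers LP replicates 1 and 2 stood at 0.522 and 0.728 and LP replicate 3 at -0.111. HA libraries lay between -0.256 and -0.129 on them. On the mitochondrial list LP replicate 2 stood at 0.525, against 0.102 and 0.101 in the other LP libraries. No single gene passed the edgeR test. Nub1 stood at 71.6 ± 0.368 CPM in LP and 70.4 ± 0.97 CPM in HA, and Pomc at 50.04 ± 1.77 and 79.0 ± 13.4 CPM (SD, n = 3 each).

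Of 24 immediate early genes, 21 had a higher estimate in HA (median 0.27, camera adjusted p = 1.52e-13). The adjusted p was 0.0874 with an estimated correlation and 0.00192 with the mixed test of fry. Over all genes 0 changed, and 8 were higher when adjusted over the list alone. Nr4a1 stood at 17.6 ± 1.82 CPM in LP and 26.2 ± 1.14 CPM in HA, a log2 fold change of 0.57 (SE 0.088) with an adjusted p of 0.399 (edgeR). Junb stood at 26.2 ± 1.29 and 37.7 ± 3.98 CPM, Nr4a3 at 13.5 ± 0.971 and 20.1 ± 2.86 CPM, and Fos, a subunit of the transcription factor AP-1, at 27.6 ± 4.07 and 40.7 ± 0.56 CPM. HA replicate 3, the library highest in meningeal markers, was also highest on this list, with a mean deviation of 0.352 against 0.054 and 0.117 in the other HA libraries. Without LP replicate 3 and HA replicate 3 the median was 0.24 and the adjusted p 4.46e-07. DESeq2 called Nr4a1, Junb, Nr4a3 and Fos higher (adjusted p between 0.0017 and 0.0187).

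All 17 striatal markers had a lower estimate in HA (median -0.50, camera adjusted p = 9.35e-16; 0.215 as adjusted p with an estimated correlation), with 0 changed over all genes and 9 lower when adjusted over the list alone. Ppp1r1b stood at 49.2 ± 34.4 CPM in LP and 12.5 ± 3.16 CPM in HA. Pde10a stood at 92.2 ± 25.7 and 59.6 ± 5.19 CPM. The median was -0.306 without LP replicate 2, and without LP replicate 3 edgeR called Ppp1r1b and Pde10a lower (adjusted p = 0.00712 and 0.04). Without LP replicates 1 and 2, the libraries highest in Adora2a, the adjusted p was 0.45 and the median -0.086. Monoaminergic genes were lower for 20 of 22 members (adjusted p = 0.000187; 0.0874 as adjusted p with an estimated correlation), with Drd2 at 21.7 ± 2.81 and 15.3 ± 1.45 CPM and Th, the enzyme gene of dopamine synthesis, at 34.2 ± 6.55 and 25.4 ± 0.926 CPM. Markers of cortex and hippocampus were lower for 15 of 19 members (0.000532; 0.289 as adjusted p with an estimated correlation), and GABAergic synapse genes for 24 of 27 (0.000104; 0.445 as adjusted p with an estimated correlation). Without LP replicates 1 and 2 neither of these last lists was called (0.497 and 0.505), while monoaminergic genes were (0.000279).

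All 13 respiratory chain genes of the mitochondrial genome had a lower estimate in HA (median -0.18, camera adjusted p = 4.72e-10; 0.301 as adjusted p with an estimated correlation), with 0 changed over all genes and 2 lower when adjusted over the list alone. The median was -0.107 without LP replicate 2. The complex I gene mt-Nd6 stood at 899.7 ± 23.1 CPM in LP and 805.7 ± 40.5 CPM in HA. Cytosolic heat shock genes were higher for 14 of 15 members (median 0.11, adjusted p = 8.65e-07; 0.309 as adjusted p with an estimated correlation), with 2 higher when adjusted over the list alone. Dnajb1 stood at 95.8 ± 5.71 and 125.0 ± 9.79 CPM and Hsph1 at 369.5 ± 22.4 and 434.9 ± 7.85 CPM, and DESeq2 called both higher (adjusted p = 0.00336 and 0.0412). The median of the list was 0.196 without LP replicate 2 and 0.056 without HA replicate 1, and it was called in both (adjusted p = 2.65e-10 and 7.37e-05).

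The 10 named genes of smallest p had an adjusted p of 0.399 (edgeR). Besides Nr4a1 and Junb they included Ccdc117 (chromosome 11, 5528887 to 5542187), at 26.1 ± 1.32 CPM in LP and 36.5 ± 2.8 CPM in HA, and Fam214a, at 66.3 ± 4.44 and 49.8 ± 1.01 CPM. Lifr, a cytokine receptor gene, stood at 53.4 ± 1.19 and 42.2 ± 1.73 CPM, and Kcnj4 at 14.8 ± 4.0 and 6.75 ± 0.921 CPM. Syt6, Cpne5 and Dedd2 had log2 fold changes of -0.43, -0.41 and 0.31. Of these genes DESeq2 called Ccdc117, Fam214a, Lifr, Kcnj4, Syt6 and Cpne5 (adjusted p between 0.0017 and 0.011), and edgeR called Kcnj4 without LP replicate 3 (0.04).

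Pomc (50.04 CPM in LP, 79.0 CPM in HA) had a log2 fold change of 0.66 (SE 0.154) with an adjusted p of 0.641 over all genes (edgeR). DESeq2 called it higher, with a log2 fold change of 0.658 and an adjusted p of 0.00609, in a comparison where DESeq2 made 7 calls on simulated counts with 0 changed genes. On the pituitary markers the HA libraries stood at -0.084, 0.291 and 0.497 and the LP libraries at -0.091, 0.033 and 0.307. The pituitary list was not called in HA against LP (camera adjusted p = 0.212). Whether pituitary tissue contributed to the Pomc counts was not tested. Pomc was the 1 member of the appetite neuropeptides higher when adjusted over the list alone. That list was not called by camera (adjusted p = 0.17, and 0.0357 and lower without LP replicate 2). Energy balance receptors and signalling was not called by camera either (0.583), but passed the mixed test of fry (adjusted p = 0.0133). Of its members, 2 were higher when adjusted over the list alone. Agrp stood at 11.2 ± 1.72 CPM in LP and 14.1 ± 2.93 CPM in HA, Npy at 30.8 ± 2.41 and 35.5 ± 7.13 CPM, and Cartpt at 85.2 ± 3.42 and 100.1 ± 5.44 CPM. Lepr and Mc4r had log2 fold changes of 0.25 (SE 0.486) and -0.26 (SE 0.253). Hspa5 stood at 628.7 ± 28.5 and 652.0 ± 78.3 CPM, and Ddit3, Atf4 and Xbp1 had log2 fold changes of -0.007, 0.013 and -0.018.

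**Figure D3:**
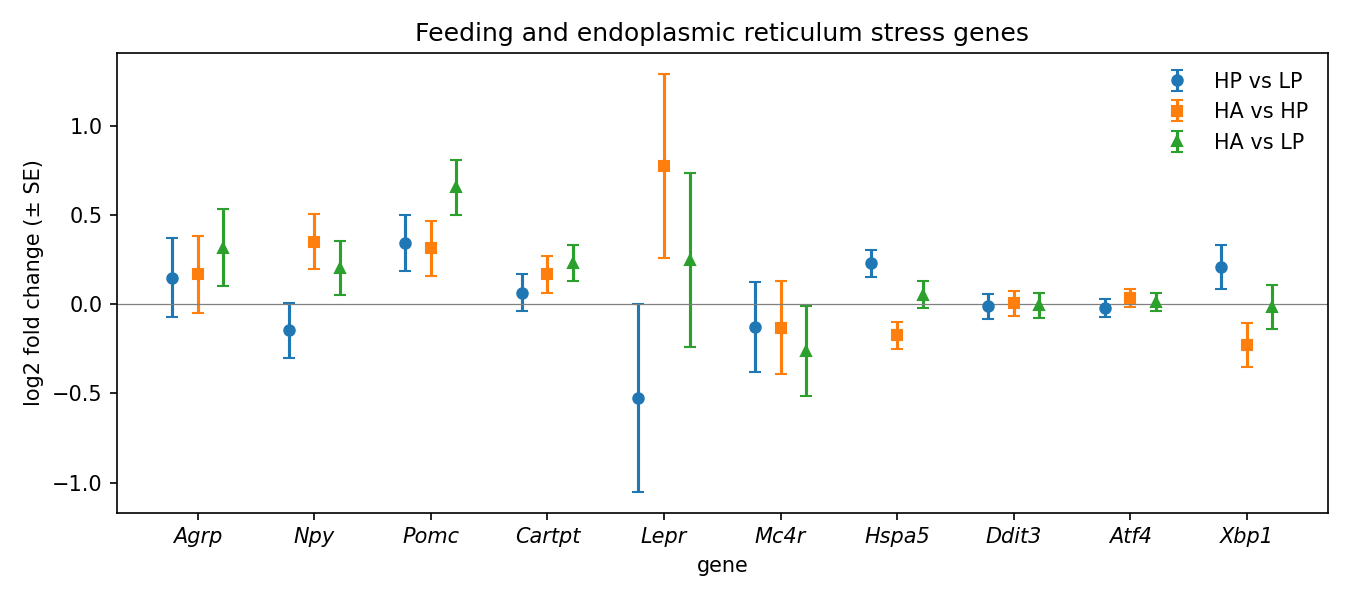
Log2 fold changes (edgeR, bars show the SE) of 10 feeding and endoplasmic reticulum stress genes in HP against LP (circles), HA against HP (squares) and HA against LP (triangles). Pomc has the largest estimate relative to its SE, 0.66 with an SE of 0.154 in HA against LP, and none of the 10 passed the adjusted edgeR test over the 9 libraries in any comparison.

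The other 13 called lists were each lost without at least 1 library, and their adjusted p with an estimated correlation lay between 0.349 and 0.726. Presynaptic vesicle release (adjusted p = 2.38e-05) and glutamatergic synapse genes (8.51e-05) were lower, and without HA replicate 3 their adjusted p were 0.141 and 0.0534. Glucocorticoid-responsive genes (0.034, up to 0.842 without LP replicate 3, HA replicate 1 or HA replicate 2) and autophagy genes (0.0354, up to 0.289 without LP replicate 3, HA replicate 2 or HA replicate 3) were lower. Endothelial and mural markers (0.000118, up to 0.922), interferon response genes (0.00123, up to 0.951) and the unfolded protein response (0.0278, up to 0.349) were higher, and each was lost without LP replicate 1 or HA replicate 3. Without HA replicate 3 the last 2 had medians of -0.023 and -0.014. Matrix and collagen genes were higher (0.00103) but called lower without HA replicate 3 (0.00958, median -0.494), and were lost without LP replicate 1 or LP replicate 2, with an adjusted p up to 0.2. Inflammatory genes were higher (0.0345, up to 0.957) and lost without LP replicate 1, LP replicate 2 or HA replicate 3. Cytosolic ribosomal proteins were higher (0.00266; 0.2 without LP replicate 1). Cell cycle genes were higher (0.00374; up to 0.121 without LP replicate 3 or HA replicate 3). Tanycyte markers were higher (0.0324; up to 0.767 without LP replicate 1, LP replicate 3 or HA replicate 3), as were ependymal markers (0.0477; up to 0.617 without LP replicate 2, LP replicate 3, HP replicate 1, HA replicate 1 or HA replicate 3). Meningeal fibroblast markers were not called (0.172), but had an adjusted p of 0.0146 with the replicate number as a block. They were called higher without LP replicate 3, HA replicate 1 or HA replicate 2 (adjusted p up to 0.000809) and lower without HA replicate 3 (8.13e-06, median -1.514). Tanycyte (0.0523), inflammatory (0.0594), autophagy (0.0914) and ependymal (0.0773) lists were not called when scaled by library totals.

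In HA against LP edgeR called 0 of 17546 genes, with a smallest adjusted p of 0.399, while 1146 had an unadjusted p under 0.05 where chance would give 877. DESeq2 called 27 genes and limma-voom 0. On simulated counts in which HA and LP did not differ, DESeq2 made 7 calls, and edgeR and limma-voom made 0. The simulated counts held only the filtered genes, while DESeq2 was run on the real counts unfiltered. The edgeR count was 16 without LP replicate 3, 2 without LP replicate 1, 1 without HP replicate 3 or HA replicate 3, and 26 without LP replicate 3 and HA replicate 3. The number of lists called was 20, against 12 without LP replicates 1 and 2.

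Whether 4-PBA moved genes against the diet difference was asked by correlating log2 fold changes across the 17546 genes, which are not independent replicates. HP against LP and HA against HP, which share the HP libraries, correlated at -0.58 (Pearson) and -0.46 (Spearman). Simulated data with no difference between groups gave -0.508 (SD 0.0135) and -0.455. The covariance was -0.0549 against a simulated -0.0379. Simulated libraries were drawn independently of each other, whereas same-numbered HA and LP libraries correlated at 0.256, 0.144 and 0.486 in their deviations from the group means. Signal shared by HA and LP libraries would make this covariance more negative. Deviations from group means cannot show by how much, and this was not estimated. Sharing of the HP libraries is already part of the simulated values. The 3 HP libraries cannot be split into parts of at least 2 each. Spread in them that the simulation leaves out may therefore also add to the excess, and this was not checked. Pearson's value was -0.269 without LP replicate 3. The simulated -0.508 holds for all 9 libraries, and no value was simulated for that fit. The 2 genes called in both comparisons, Nub1 and Gm6472, had opposite directions, where simulation gave 0.12 shared calls and independent lists would share 0.000114.

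HP against LP and HA against LP, which share the LP libraries, correlated at 0.39 (Pearson) and 0.40 (Spearman), against simulated values of 0.495 (SD 0.0139) and 0.448. The covariance was 0.0328 against a simulated 0.0366. The observed values thus lay below the simulated ones, by 0.102 for Pearson's value. Signal shared by HA and LP libraries, which the simulation leaves out, would lower this covariance too, by an amount that was not estimated. Pearson's value was 0.598 without LP replicate 3, and 0.769 without LP replicates 1 and 2. With fewer shared LP libraries the value for unchanged groups rises too. No value was simulated for these fits, so they cannot be set against 0.495. The 3 LP libraries could not be split into parts of at least 2 each.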

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

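The fits without LP replicate 3 and HA replicate 3 and without LP replicates 1 and 2 were chosen after seeing the data, and the other alternatives before the data were examined. The cause was not tested for any of the moves given here, except where fewer genes or libraries follow from the alternative itself. For HP against LP, where edgeR called 2 genes, DESeq2 called 32, the fit to the 6 libraries compared 5, limma on log2(FPKM + 1) 1, the same without a filter 4, and a threshold that adds an absolute log2 fold change of 1 called 0 (edgeR, with 1081 genes at an unadjusted p under 0.05). It was 1 to 22 when single libraries were left out, with 22 without LP replicate 3, and 48 without LP replicate 3 and HA replicate 3. For HA against HP, where edgeR called 2, DESeq2 called 8, the added fold threshold left 0 (915 genes at an unadjusted p under 0.05), single libraries left out gave 1 to 9, with 9 without HA replicate 3, and leaving out LP replicate 3 and HA replicate 3 gave 11. For HA against LP, where edgeR called 0 (1146 at an unadjusted p under 0.05), DESeq2 called 27, the fit to the 6 libraries compared 2, limma on log2(FPKM + 1) without a filter 1, single libraries left out 0 to 16, with 16 without LP replicate 3, and leaving out LP replicate 3 and HA replicate 3 gave 26.

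Gene lists called numbered 15, 18 and 20 for HP against LP, HA against HP and HA against LP. With an estimated correlation and with fry's directional test the numbers were 0, 0 and 0. The smallest adjusted p were 0.12, 0.317 and 0.0874 with an estimated correlation and 0.119, 0.323 and 0.0769 with fry's directional test. Leaving out single libraries gave 12 to 16, 8 to 20 and 15 to 22 lists. For HA against HP the lowest was without HA replicate 3, and 10 lists were called without LP replicate 3 and HA replicate 3. For HA against LP 12 were called without LP replicates 1 and 2. Of the lists called, 6 of 15, 3 of 18 and 7 of 20 were called with every single library left out.

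The correlation of HP against LP with HA against HP ranged from -0.705 (without HP replicate 3) to -0.269 (without LP replicate 3). That of HP against LP with HA against LP ranged from 0.279 (without HA replicate 1) to 0.598 (without LP replicate 3), and was 0.515 without LP replicate 3 and HA replicate 3 and 0.769 without LP replicates 1 and 2.

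With the replicate block, 4, 2 and 0 genes and 14, 18 and 21 lists were called for HP against LP, HA against HP and HA against LP, and the gene length offset with the replicate block gave 4 genes for HP against LP. The correlations with the replicate block were -0.581 and 0.407. Same-numbered libraries correlated at 0.137, -0.028 and 0.159 for HP and LP and at 0.082, 0.004 and 0.118 for HA and HP. Not all passed 0.1, and not every library correlated best with its own number. With 3 libraries per group this cannot exclude a pairing, and HP and HA carry the same title code at each number. For HP against LP the block ended the call of the blood cell markers (adjusted p = 0.102). For HA and LP the block changed no call other than that of the meningeal markers. Of 7467 values of named genes under alternatives, 7304 kept their direction and side of the threshold, 22 lost a call, 72 gained one, 69 changed sign with no call in either fit, and 0 reversed a call. The 22 were 1 each for Nub1 in HP against LP and in HA against HP, under the added fold threshold, and 10 each for Gm6472, whose adjusted p reached 0.348 and 0.179. Depth limits genes of few counts, and the 17546 genes tested leave out the rest of the 54532.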

Other observations

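The tests of the sequence match of Gm6472, of the summed count of Rps7 and Gm6472, of gene levels and of the striatal and immediate early lists without chosen libraries were chosen after the results were seen, while the counts of other splits were planned. Genes named here outside the naming rule were chosen after their values were seen. Glp1r, the receptor gene of the satiety hormone GLP-1, had means of 4.53, 6.18 and 8.07 CPM in LP, HP and HA, with a log2 fold change of 0.82 (SE 0.171) in HA against LP and an adjusted p of 0.549 over all genes (edgeR), while DESeq2 called it. Irs1, which relays insulin signals, had a log2 fold change of 0.36 (SE 0.085) and an adjusted p of 0.641. These were the 2 members of energy balance receptors and signalling that were higher when adjusted over the list alone. The thyroid hormone pathway held Hr, a corepressor gene that thyroid hormone induces, with log2 fold changes of -0.33 (SE 0.079) in HA against HP and -0.37 (SE 0.079) in HA against LP and adjusted p of 0.847 and 0.611 (edgeR), while DESeq2 called it in HA against LP. Pdk1, a kinase gene that restrains pyruvate use, had a log2 fold change of 0.54 (SE 0.114) in HP against LP and an adjusted p of 0.455 (edgeR). It was called by DESeq2, in the fit to the 6 libraries compared, without HA replicate 3 and without LP replicate 3 and HA replicate 3.

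Some genes stood at separate levels that did not follow the groups. Nt5dc3 stood at 65.3 to 71.0 CPM in HP and at 63.1 CPM in HA replicate 3, against 19.4 to 20.9 CPM in the other 5 libraries. The HP and LP libraries did not overlap for Nt5dc3, and the fit to the 6 libraries compared called it in HP against LP. Its other calls, in HP against LP and in HA against HP, came only in fits that left out HA replicate 3. Pop4 stood at 16.2 CPM in LP replicate 3 and at 17.5 and 18.4 CPM in HP replicates 1 and 2, against 5.88 to 7.65 CPM in the other 6. Of 26 genes whose levels parted 3 libraries from 6, 3 followed a group (Nub1, Akr1c14 and Mx2), where 0.93 would follow one by chance. Striatal markers had a median log2 fold change of -0.109 in HP against LP without LP replicates 1 and 2.

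Gm6472 was higher in HP than in LP and HA, while Rps7 was lower. A candidate explanation is reads shared between the pair. The best match of Gm6472 was Rps7 at 99.4% identity, and the summed count had a log2 fold change of 0.004 in HA against HP, as a move of reads within the pair would give. Both results go with shared reads, which could come from a sequence difference in Rps7 among the outbred pups, which the counts cannot show. Other close matches of Gm6472, such as Gm9493 at 98.9% identity, were not part of the sum. A change of Rps7 or Gm6472 with diet or 4-PBA stays open and was not tested separately.

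Nub1 was lower in the 3 HP libraries than in the other 6. HP and HA hold the same title codes in equal numbers, so the codes cannot account for their difference, while code and diet cannot be told apart in comparisons with LP. Inherited variants that fell unevenly on the groups may be the source, as ICR mice are outbred and Nt5dc3 and Pop4 show level differences across groups. The count of 3 genes that follow a group had a one-sided binomial p of 0.0643. It includes Nub1 itself, the gene in question, and the bounds for this test were set after the value was seen. The test therefore does not decide. Effects of the diet and of 4-PBA cannot be told apart from such variants here, because the labels give neither litters nor genotypes.

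Immediate early genes were higher in HA than in LP. Tissue of the meninges and pituitary in HA replicate 3 and LP replicate 3 is argued against as the whole cause, since the median log2 fold change without both was 0.24. Handling or time of dissection that differed between groups could also move these genes and was not tested, since the labels record neither. The list of circadian clock genes was not called in HA against LP (camera adjusted p = 0.848), which does not exclude a difference in time. Effects of the diet and of 4-PBA stay open and were not tested separately.

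Splits of the 6 libraries of each comparison into other groups of 3 number 10 with the real one, too few for a share under 0.05. For HP against LP the real split gave 2 genes and the highest other 2, with 2 of the 10 splits giving as many. It gave 15 lists and the highest other 21, with 5 splits giving as many. For HA against HP it gave 2 genes and the highest other 3, with 2 splits as large, and 18 lists against 25, with 3 as large. For HA against LP it gave 0 genes and the highest other 2, with all 10 as large, and 20 lists against 25, with 4 as large. The other splits of HA and LP that part all same-numbered pairs gave at most 2 genes and 22 lists.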
